A study of Homo sapiens with 8 samples.

How the data were processed

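Total RNA was extracted with Trizol from A549 and PC9 cells stably infected with a retrovirus carrying EN2 or with the Neo vector control, per the labels. A549 was grown in F-12K medium and PC9 in DMEM. cDNA was made from the RNA, labelled with biotin and hybridised to single-colour arrays. The table held 49495 probe sets on 8 arrays, in 4 groups of 2. The deposited values were on the log2 scale and had been summarised with RMA per the submitters' processing notes. The RMA version and the array annotation used upstream are not given in the sources used here. The labels do not say whether all arrays were normalised in a single run. Quantiles of the arrays lay close together within a line and apart between the lines. At the 25th percentile the arrays of a line spanned 0.012 in A549 and 0.038 in PC9, and A549 was 0.42 higher than PC9. No probe set had the same value in an array of each line (0%), against 0.519% to 0.713% for arrays of the same line. The scale of the lines relative to each other is therefore not known, and differences between lines carry this limit. The number of arrays limits the precision of every value.

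Probe sets were named from the array annotation with current symbols of the GRCh38.p14 gene annotation. That reference was used only for names and for the order of neighbouring genes, and no coordinates were used otherwise. Of the probe sets, 45284 carried 1 symbol, 1333 carried several and 2878 carried none. By Entrez identifier, 45214 matched the reference. A gene was represented by the probe set with exactly 1 symbol that had the highest mean over the 8 arrays. This gave 18244 genes, of which 11826 had more than 1 probe set. No filter on dim probe sets was applied. As a measure of background, the 95th percentile of the 100 ERCC spike-in probe sets was 4.38 in A549 and 3.92 in PC9.

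Genes were tested with limma 3.58.1 in R 4.3.3. A model with a mean per group was fitted to all 8 arrays with lmFit, followed by eBayes with an intensity trend, on 4 residual degrees of freedom. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 18244 genes of each comparison. A gene was called at an adjusted p below 0.05. The comparisons were EN2 against vector in A549, the same in PC9, the difference between these changes, their average, and the vector controls of A549 against those of PC9. An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333, so the p-values come from limma's test. The labels do not say that the replicates were separate cultures. The p-values then measure only the spread between these samples, which may be technical.

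Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, for lists with at least 5 measured members. Of 36 lists, 35 were tested, and the list of mitochondrially encoded genes was not analysed here. List p-values were adjusted by the Benjamini-Hochberg method over the 35 lists of a comparison. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance in a single direction without comparing them with other genes, were run beside it. The overlap of called genes between lines was tested with Fisher's exact test across genes, which are not independent. That test also ignores that both lines share the same estimate of spread per gene.

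The comparisons, tests, gene lists and the rule for naming genes were chosen before the data were examined. Named genes were EN2, the 12 highest and 12 lowest changes in each line among called genes whose EN2 arrays both lay on the same side of both control arrays, and the 6 highest and 6 lowest differences between the lines. Of genes called in both lines, the 6 with the largest smaller change were named in each direction and among opposite calls. The 6 highest and 6 lowest differences between the vector controls, and up to 4 members of a described list with the smallest p, were also named. Symbols of small or uncharacterised RNAs and loci were left out. Other genes are said to have been chosen after their values were seen.

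Alternatives were a constant or a robust prior variance, the brighter genes alone, quantile normalisation over all arrays, median centring, the mean of all probe sets of a gene, every probe set tested, the arrays of a line alone, the replicate number as a block, limma's treat against a 1.2-fold change, and leaving out each array in turn. With an array left out, the lone array of its group is assumed to vary like the other groups. After the data had been seen, fits were added with the 18S rRNA control signal as a covariate and without the 2 A549 arrays of lowest and highest 18S rRNA signal. The method was tested on simulated data built from the A549 comparison of 18244 genes, with 200 changed genes in each of 20 simulations. It recovered 78.2% of genes changed by 0.5 on the log2 scale, 99.9% at 1 and 100% at 2, with a mean of 13.9 false calls (6.98% of calls). In 20 simulations on the PC9 arrays, a list shifted by 0.3 was called 20 times, and other lists were called 2 times. The lists called in the real PC9 data had smaller means, from −0.15 to 0.092, and shifts of such sizes were not simulated. Noise was drawn independently for each gene in all simulations, without an 18S rRNA gradient. The simulations therefore do not show how often lists of correlated genes are called falsely.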

Results

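Gene expression was measured in A549 and PC9, established human lung adenocarcinoma cell lines, a form of non-small cell lung cancer. Cells of each line carried a retrovirus with EN2, which encodes an engrailed homeobox transcription factor of midbrain and hindbrain development, or the Neo vector as control. Each of the 4 groups had 2 arrays. The array medians on the log2 scale were 6.33 to 6.35 in A549 and 6.102 to 6.109 in PC9. Arrays of a group correlated across probe sets at r = 0.997. EN2 and vector arrays of a line correlated at 0.992 to 0.997, and arrays of different lines at 0.891 to 0.900. The 18S rRNA control probe sets, given as the mean of 3, read 11.66 and 12.12 in the A549 EN2 arrays against 12.44 and 12.74 in the A549 vector arrays. In PC9 they read 6.049 to 6.095 on the arrays of both groups.

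The first question was whether the cells differed in EN2 itself. In A549, the brighter EN2 probe set read 7.67 ± 0.064 with EN2 and 6.52 ± 0.067 with vector (SD, n = 2 arrays each). EN2 rose 2.21-fold in A549 (log2 change 1.15 ± 0.091 SE, Benjamini-Hochberg adjusted p = 0.00028 by limma over 18244 genes). In PC9 the same probe set read 6.32 ± 0.11 with EN2 and 5.82 ± 0.055 with vector (SD, n = 2 arrays each). This log2 change of 0.50 did not pass limma's test (adjusted p = 0.0801), although both EN2 arrays lay above both vector arrays. The difference in EN2 change between the lines, 0.65 ± 0.13, did not pass either (adjusted p = 0.0638). The dimmer EN2 probe set had log2 changes of 0.050 in A549 and 0.16 in PC9, and neither passed. With the mean of the EN2 probe sets the change was 0.60 in A549 (adjusted p = 0.0179) and 0.33 in PC9 (adjusted p = 0.453). The paralog EN1 read 3.45 to 3.53 in all groups, below the spike-in background of both lines. The A549 call of EN2 ended with the 18S rRNA signal as a covariate (1.11, adjusted p = 0.13) and without the 2 outer A549 arrays of that signal (1.15, adjusted p = 0.0697).

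**Figure D1:**
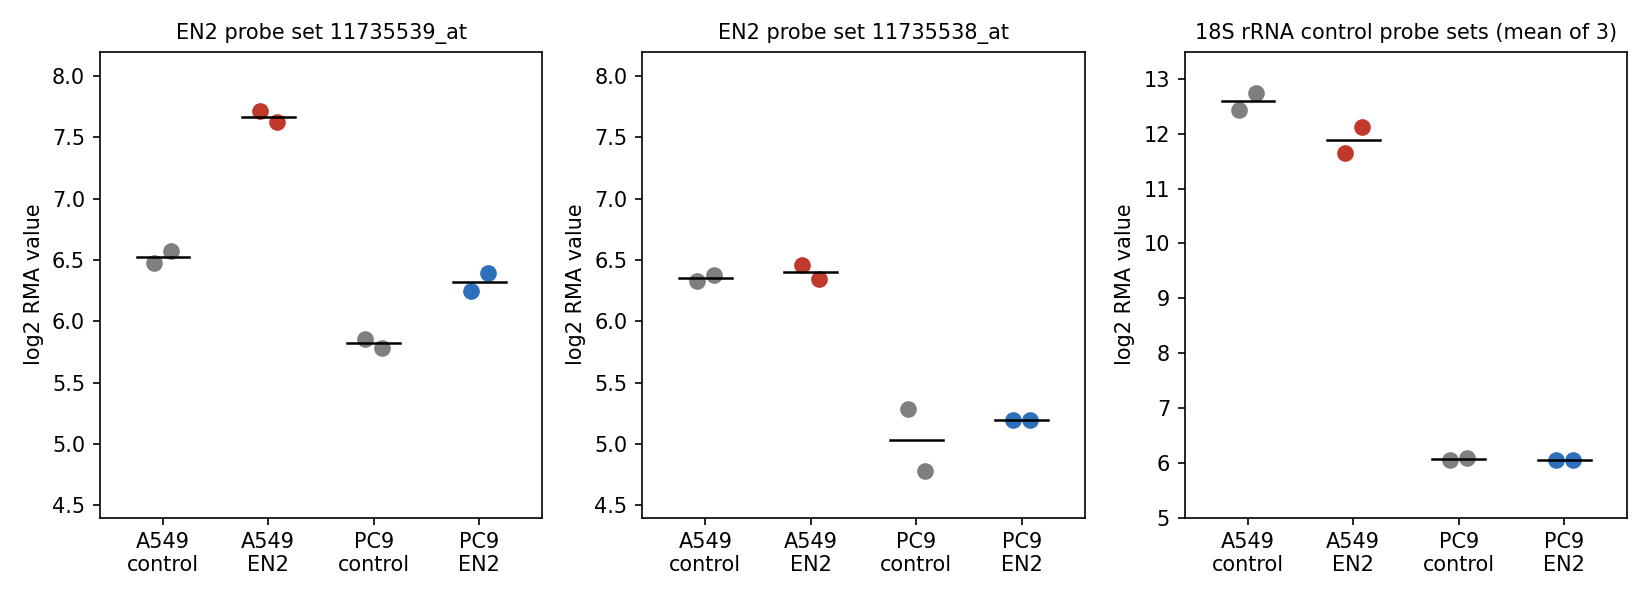
Log2 RMA values of both EN2 probe sets and of the 18S rRNA control probe sets on every array, with a bar at the mean of each group of 2 arrays. The A549 EN2 arrays sit near 7.7 and the vector arrays near 6.5 on the brighter EN2 probe set, and the 18S rRNA signal differs between A549 groups and by 6.18 between the lines.

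The comparison of EN2 with vector in A549 asked which genes change with EN2 in this line. TFF1, which encodes a secreted trefoil peptide of mucous epithelia, rose 6.39-fold, from 7.23 ± 0.077 to 9.90 ± 0.095 (SD, n = 2 arrays each; limma adjusted p = 1e-05). FN1, the gene of the matrix protein fibronectin, rose 2.59-fold, to 12.29 ± 0.035 (adjusted p = 0.000181). EHF, an epithelial ETS-family transcription factor, fell 4.11-fold, from 7.04 ± 0.29 to 5.00 ± 0.056 (adjusted p = 8.12e-05). CDH1, the gene of E-cadherin, fell 2.17-fold, from 9.68 ± 0.054 to 8.57 ± 0.11 (adjusted p = 0.000384). In all, 287 genes rose and 209 fell among 18244, of which 28 and 21 changed at least 2-fold.

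Among the other genes with the highest A549 changes were GREM1, a secreted BMP antagonist (log2 change 1.86), IQGAP2, a cytoskeletal scaffold (1.84), and DIO2, the deiodinase that activates thyroid hormone (1.83). The carbonic anhydrase gene CA2 rose by 1.64, the pentraxin gene NPTX1 by 1.61 and GASK1B by 1.56 on the log2 scale. PLPP3, a lipid phosphate phosphatase, rose by 1.48, the nuclear receptor gene NR4A3 by 1.40, XYLT1, which starts glycosaminoglycan chains, by 1.38, and the lectin-like receptor gene KLRC1 by 1.37. The vector level of GASK1B, 4.12, was below the spike-in background. In PC9, IQGAP2, GASK1B, XYLT1, KLRC1 and NTS were below it in both groups, so their PC9 change cannot be read. On the lower side, PKIB, an inhibitor of protein kinase A, fell (−2.29), as did THSD7A (−1.91). The zinc finger genes ZNF57 (−1.64), ZNF77 (−1.42) and ZNF555 (−1.35) fell together with ANXA10 (−1.63) and the nuclear receptor gene NR5A2 (−1.46). The neurotensin gene NTS (−1.22), TM4SF4 (−1.18) and GPX2, a glutathione peroxidase (−1.14), also fell. The adjusted p-values of these 24 named genes ran from 1e-05 for TFF1 to 0.0205 for NR4A3. In each of the 24, both EN2 arrays lay beyond both vector arrays, and all probe sets of the gene had the same sign.

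The A549 counts rested partly on the 2 arrays with the lowest and highest 18S rRNA signal: 54 genes rose and 58 fell without EN2 replicate 1, and 57 rose and 59 fell without vector replicate 2. With the 18S rRNA signal as a covariate, 5 genes rose and 15 fell, and without both arrays 9 and 16. With the covariate 4 of the 12 higher and 7 of the 12 lower named genes stayed called, TFF1 and EHF among them, while the median SE of the 496 genes went from 0.096 to 0.18. FN1 kept its size (1.31, adjusted p = 0.0868), as did CDH1 (−0.98, adjusted p = 0.162), and both lost the call with the wider SE. GREM1 went to 0.66 (adjusted p = 0.811), NR4A3 to 0.25 (adjusted p = 1) and GPX2 to −0.71 (adjusted p = 0.162), while NTS went to −2.18. Without both arrays GREM1 was 1.24 and NR4A3 0.78, neither called, and on the A549 arrays alone GREM1 (adjusted p = 0.0835), NR4A3 (adjusted p = 0.155) and NTS (adjusted p = 0.146) were not called. Of 53 other called list members in A549, LCN2 alone stayed called with the covariate, and 23 shrank by more than 1.5 times, such as IRAK2 (0.052), RIGI (0.10), CYP4F11 (−0.54) and ALDH3A1 (−0.36).

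**Figure D2:**
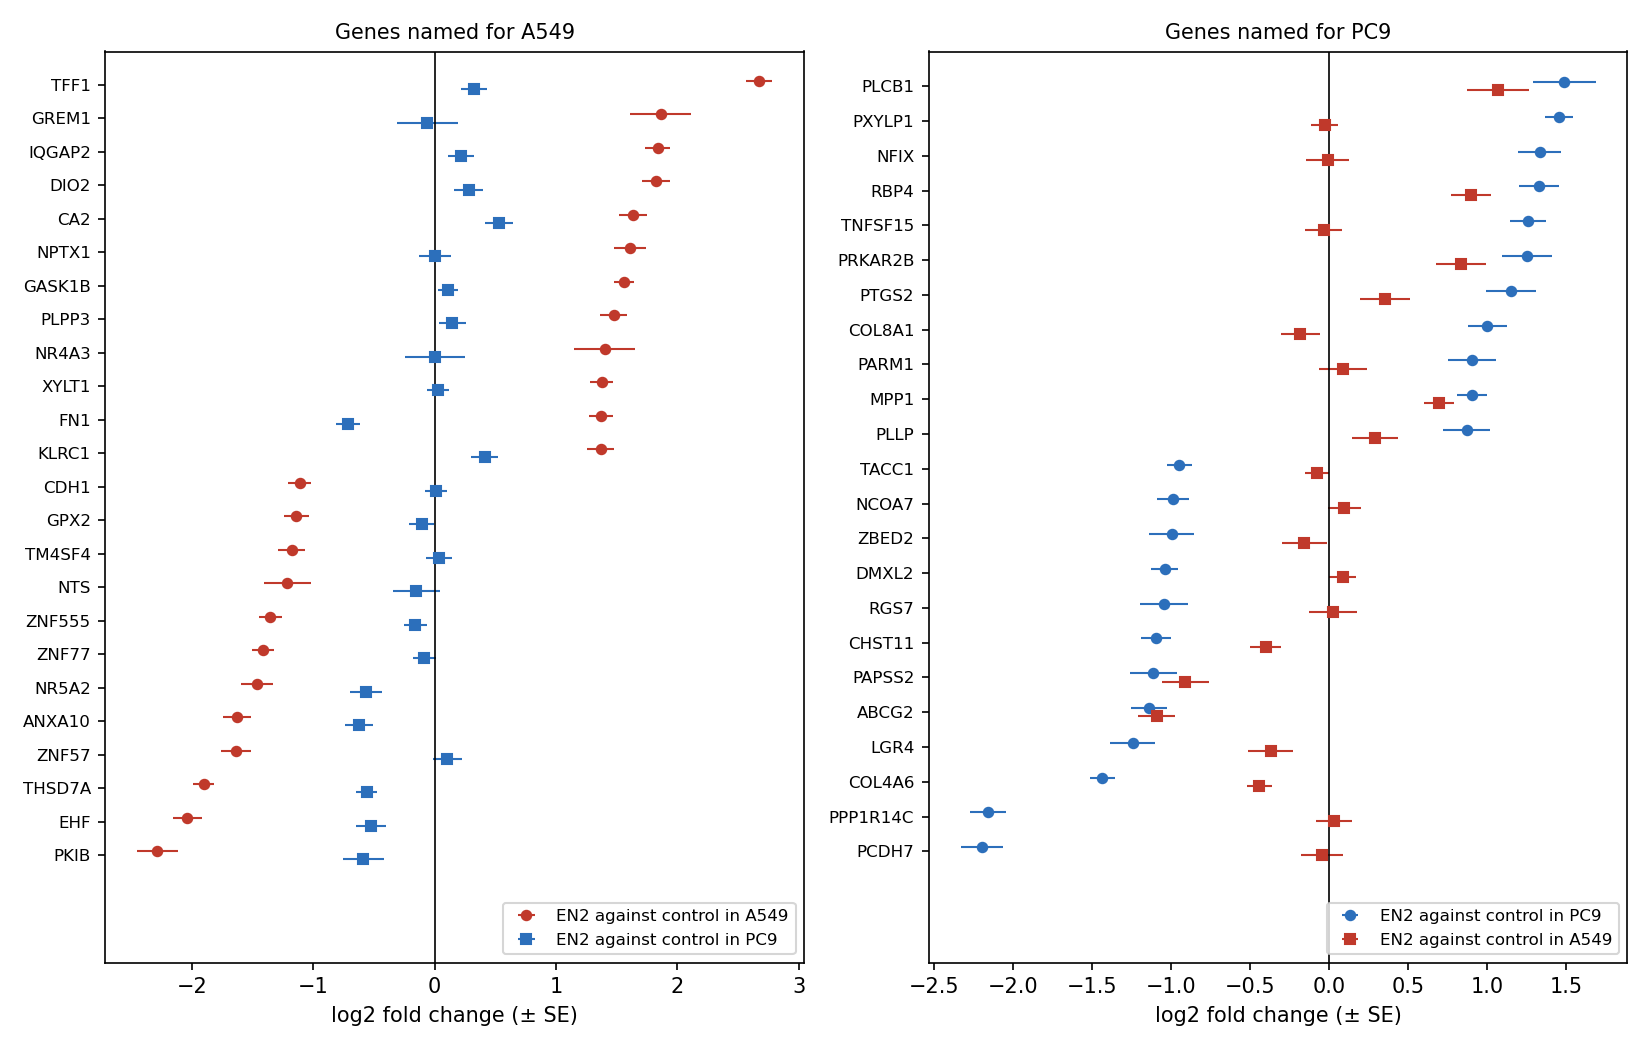
Log2 fold changes (x axis, ± SE from limma) of the 24 genes named for A549 and the 23 named for PC9, in rank order, with the same gene's change in the other line as squares. FN1 lies at 1.37 in A549 and −0.72 in PC9, and ABCG2 near −1.1 in both.

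Targets of NRF2, the transcription factor of the oxidative stress response, fell as a group in A549. Of 26 measured, 6 fell, none rose and 20 did not pass, and adjusted over the list alone 17 fell and none rose. GPX2 fell by 1.14, CYP4F11 by 1.07, ALDH3A1 by 0.76 and AKR1C1 by 0.52 on the log2 scale. The mean log2 change was −0.29 (camera adjusted p = 4.08e-13 over 35 lists), with adjusted p = 0.194 with an estimated correlation. The p53 target list behaved alike, with 7 of 22 measured members lower, none higher and 15 not called, or 12 lower adjusted over the list alone. MDM2, the ubiquitin ligase that degrades p53, fell by 0.84, the repair gene DDB2 by 0.53, the apoptosis gene BAX by 0.51 and CCNG1 by 0.37. The mean was −0.26 (adjusted p = 1.94e-07; adjusted p = 0.194 with an estimated correlation). Both lists stayed called with the 18S rRNA signal as a covariate, at −0.16 for NRF2 targets, smaller by more than 1.5 times, and −0.40 for p53 targets, larger by more than 1.5 times.

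Of 24 epithelial markers measured in A549, 5 fell, none rose and 19 did not pass, and adjusted over the list alone 8 fell and 1 rose. CDH1, the adhesion molecule gene EPCAM (−0.77), the keratin gene KRT19 (−0.70) and the integrin gene ITGB4 (−0.39) fell. The list mean was −0.15 (camera adjusted p = 0.00224; adjusted p = 0.519 with an estimated correlation). Mesenchymal markers and transcription factors of the epithelial-mesenchymal transition were not called as a list (adjusted p = 0.869). Of 26 measured, FN1 rose, while ACTA2, smooth muscle actin, fell by 0.93 and SERPINE2 by 0.44, and adjusted over the list alone 7 rose and 3 fell. Their mean of 0.063 and the test's direction were positive, while their median was −0.042. Of 36 subunits of respiratory complex I, NDUFS3 (−0.38) and NDUFA10 (−0.34) fell, none rose and 34 did not pass, or 5 lower adjusted over the list alone. That list had a mean of −0.13 (adjusted p = 1.94e-07; adjusted p = 0.549 with an estimated correlation), and its call ended with the 18S rRNA covariate (−0.027, adjusted p = 0.474).

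Sterol and fatty acid synthesis genes had a mean of −0.10 in A549 with none of 27 members called, adjusted over the list alone included (camera adjusted p = 0.00658; adjusted p = 0.549 with an estimated correlation). Among hypoxia and glycolysis genes, SLC2A1, the glucose transporter gene, fell by 0.52, none rose and 25 of 26 did not pass, and adjusted over the list alone 2 fell and 1 rose. That list had a mean of −0.15 (adjusted p = 0.0338; adjusted p = 0.724 with an estimated correlation). The call of the hypoxia list ended without EN2 replicate 2 (−0.12) and without vector replicate 1 (−0.12), and with the 18S rRNA covariate (−0.21, adjusted p = 0.111). The call of the sterol list ended without EN2 replicate 1 (−0.048) or vector replicate 1 (−0.078), and with the covariate (−0.028, adjusted p = 0.717).

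Several signalling lists were higher in A549 with EN2. Of 38 type I interferon response genes, 5 rose, none fell and 33 did not pass, or 12 higher adjusted over the list alone. They included the RNA sensor gene RIGI (0.80), IFI44 (0.71), SAMD9 (0.66) and IFIT3 (0.55), and the list mean was 0.21 (camera adjusted p = 5.77e-05; adjusted p = 0.549 with an estimated correlation). Of 22 targets of the Hippo effectors YAP and TAZ, FOXF2 (0.85) and AMOTL2 (0.48) rose, GADD45B (−0.59) fell and 19 did not pass, or 8 higher and 2 lower adjusted over the list alone. Their mean was 0.31 (adjusted p = 0.000141; adjusted p = 0.549 with an estimated correlation). Of 21 TGF-beta/SMAD targets, the feedback regulator gene PMEPA1 (0.63) and the collagen IV gene COL4A2 (0.41) rose, none fell and 19 did not pass, or 7 higher adjusted over the list alone. Their mean was 0.19 (adjusted p = 0.000204; adjusted p = 0.194 with an estimated correlation). Of 31 NF-kB targets, IRAK2 (0.70) rose, LCN2, the gene of lipocalin, fell by 1.04 and 29 did not pass, or 6 higher and 1 lower adjusted over the list alone. Their mean was 0.27 (adjusted p = 0.000269; adjusted p = 0.549 with an estimated correlation).

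Of 28 output genes of the EGFR-RAS-MAPK pathway in A549, none rose, the ligand gene TGFA fell by 0.82 and 27 did not pass, or 2 higher and 1 lower adjusted over the list alone. Their mean was nonetheless 0.20 (camera adjusted p = 0.00679; adjusted p = 0.549 with an estimated correlation). Of 23 canonical Wnt targets, the Wnt antagonist gene DKK1 (0.70) and the transcription factor gene SOX9 (0.49) rose, none fell and 21 did not pass, or 4 higher adjusted over the list alone. Their mean was 0.13 (adjusted p = 0.0433; adjusted p = 0.395 with an estimated correlation). The list of engrailed genes and their PBX/MEIS cofactors, which contains EN2 itself, had a mean of 0.22 (adjusted p = 0.00224; adjusted p = 0.194 with an estimated correlation). In it, EN2 and the corepressor gene TLE4 (0.87) rose, none fell and 14 of 16 did not pass, or 3 higher adjusted over the list alone.

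The 18S rRNA control signal was lower in both A549 EN2 arrays than in both vector arrays. The actin 3' minus 5' control value was higher in the EN2 arrays (0.98 and 0.88) than in the vector arrays (0.79 and 0.78), and the GAPDH value was −0.049 and −0.063 against −0.065 and −0.11. With that signal as a covariate, no higher list stayed called, and the means became 0.0011 for interferon, −0.051 for YAP/TAZ, 0.14 for TGF-beta, −0.13 for NF-kB, −0.18 for EGFR-RAS-MAPK, 0.12 for Wnt and 0.14 for engrailed genes. The NF-kB call also ended without vector replicate 2 (0.10), the EGFR-RAS-MAPK call without EN2 replicate 1 (0.10) or vector replicate 2 (0.082), and the Wnt call without EN2 replicate 2 (0.14) or vector replicate 1 (0.13), while without 1 array the interferon mean ran from 0.13 to 0.29 and the YAP/TAZ mean from 0.17 to 0.44.

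**Figure D3:**
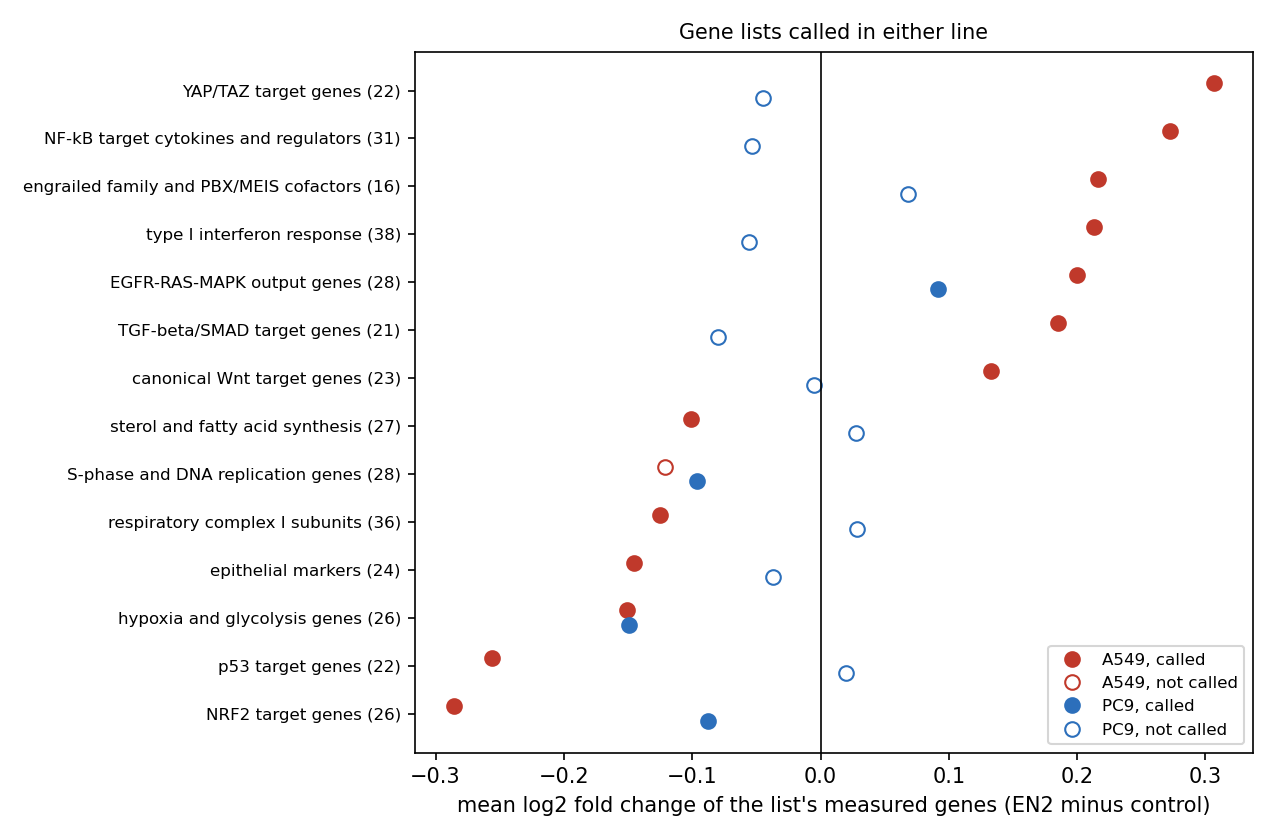
Mean log2 fold change (x axis, EN2 minus vector) of each gene list called in A549 or PC9, with its number of measured genes in brackets; filled points were called by camera at the preset correlation. NRF2 targets lie at −0.29 in A549 and −0.088 in PC9, and no list was called with an estimated correlation.

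The same comparison in PC9 asked which genes change with EN2 in this second line. PCDH7, a protocadherin gene, fell 4.59-fold, from 8.74 ± 0.27 to 6.54 ± 0.15 (SD, n = 2 arrays each; limma adjusted p = 0.000112). PPP1R14C, an inhibitor of protein phosphatase type 1, fell 4.47-fold (adjusted p = 9.02e-05), and ABCG2, a drug efflux transporter, fell 2.20-fold, from 9.66 ± 0.075 to 8.52 ± 0.099 (adjusted p = 0.00413). PXYLP1, a phosphatase of glycosaminoglycan synthesis, rose 2.74-fold, from 7.20 ± 0.0093 to 8.66 ± 0.028 (adjusted p = 0.000112). In all, 27 genes rose and 40 fell among 18244, of which 8 and 9 changed at least 2-fold.

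Other genes that rose in PC9 were the transcription factor gene NFIX (log2 change 1.33), the retinol carrier gene RBP4 (1.33), the cytokine gene TNFSF15 (1.26) and PRKAR2B, a regulatory subunit of protein kinase A (1.251). PTGS2, the inducible cyclooxygenase, rose by 1.15, PARM1 by 0.91, MPP1 by 0.90 and PLLP by 0.87 on the log2 scale. PLCB1, a phospholipase C (1.49), and the collagen gene COL8A1 (1.0) rose by the probe set that stood for the gene, but only 1 of 3 probe sets of each was positive. The vector level of PLCB1, 3.57, was below the spike-in background. Lower genes included the basement membrane collagen gene COL4A6 (−1.44), PAPSS2, which makes the sulfate donor (−1.11), the chondroitin sulfotransferase gene CHST11 (−1.10) and the G-protein regulator gene RGS7 (−1.04). DMXL2 (−1.04), ZBED2 (−0.998), NCOA7 (−0.99) and TACC1 (−0.95) fell as well, though 1 probe set of DMXL2 and 1 of NCOA7 had the other sign. The R-spondin receptor gene LGR4 fell by 1.24 on 1 of its 2 probe sets. Of the 24 PC9 genes the naming rule picks, 23 are named here. Their adjusted p-values ran from 9.02e-05 for PPP1R14C and COL4A6 to 0.0496 for PARM1, and in each both EN2 arrays lay beyond both vector arrays.

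The PC9 calls were few when any array was left out: 12 higher and 12 lower without EN2 replicate 1, 10 and 18 without EN2 replicate 2, 8 and 15 without vector replicate 1, and 7 and 12 without vector replicate 2. Of the PC9 genes the naming rule picks, 3 of 12 higher and 6 of 12 lower stayed called in every such fit, and ABCG2 lost its call without EN2 replicate 1 (−1.07) and without vector replicate 1 (−1.09).

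Of 26 NRF2 targets in PC9, AKR1B10, an aldo-keto reductase, fell by 0.51 (limma adjusted p = 0.0263), none rose and 25 did not pass, or 2 lower adjusted over the list alone. The list mean was −0.088 (camera adjusted p = 0.00139; adjusted p = 0.892 with an estimated correlation). No member of the other called lists passed, over all genes or adjusted over the list alone. Hypoxia and glycolysis genes had a mean of −0.15 over 26 members (adjusted p = 0.00668), and EGFR-RAS-MAPK output genes a mean of 0.092 over 28 (adjusted p = 0.0493). S-phase and DNA replication genes had a mean of −0.096 over 28 (adjusted p = 0.0432), and each of these 3 lists had adjusted p = 0.892 with an estimated correlation. The p53 targets (mean 0.020, adjusted p = 0.878), interferon genes (−0.056, adjusted p = 0.159) and epithelial markers (−0.037, adjusted p = 0.345) were not called in PC9. The S-phase mean turned to 0.051 without EN2 replicate 1, and its call ended without vector replicate 1 (−0.035). The hypoxia mean turned to 0.084 without vector replicate 2 and was −0.023 without EN2 replicate 1, where the EGFR-RAS-MAPK mean was 0.021, as it was 0.055 without vector replicate 2, none of them called.

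The overlap of the lines asked whether genes moved alike in both. ABCG2 fell in A549 (−1.09, limma adjusted p = 0.00139) and in PC9 (−1.14, adjusted p = 0.00413). HES1, a transcriptional repressor downstream of Notch, rose by 0.94 in A549 and 0.74 in PC9. PLCB1 (1.07 and 1.49), RBP4 (0.90 and 1.33), PRKAR2B (0.83 and 1.251), the cell cycle regulator gene RGCC (0.88 and 0.83) and MPP1 (0.70 and 0.90) also rose in A549 and PC9. DKK1 (0.70 and 0.39) and FSTL1 (0.41 and 0.72) completed the higher genes. PAPSS2 (−0.91 and −1.11), ABTB3 (−1.05 and −0.64), the aldo-keto reductase gene AKR1B15 (−0.67 and −0.60), THSD7A (−1.91 and −0.56) and COL4A6 (−0.44 and −1.44) fell in both, as did AKR1B10 (−0.37 and −0.51) and PDLIM5 (−0.37 and −0.46). The PC9 EN2 level of THSD7A (3.71), the PC9 vector level of PLCB1 (3.57) and the A549 vector level of RGCC (4.22) were below the spike-in background, so the sizes of these changes are uncertain. In A549, with the 18S rRNA covariate, ABCG2 went to −0.64 (adjusted p = 0.418), RGCC to 0.46 (adjusted p = 0.806), MPP1 to 0.43 (adjusted p = 0.801) and PAPSS2 to −1.39 (adjusted p = 0.146). Without the 2 outer arrays ABCG2 was −0.84 (adjusted p = 0.0885), and on the A549 arrays alone it was not called (adjusted p = 0.0508). FSTL1 and PDLIM5 were outside the naming rule and were chosen after their values were seen.

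FN1 moved in opposite directions, up by 1.37 in A549 and down in PC9 (−0.72, limma adjusted p = 0.0186), where the call was lost in 3 of the 4 fits with a PC9 array left out. TFPI2, a serine protease inhibitor gene (0.77 and −0.56), and the imprinted gene PEG10 (0.41 and −0.63) did the same, while PLCL2 was called at −0.45 in A549 and 0.80 in PC9. On the PC9 arrays alone FN1 (adjusted p = 0.167), TFPI2 (adjusted p = 0.198) and PEG10 (adjusted p = 0.114) were not called, nor was PEG10 on the A549 arrays alone (adjusted p = 0.115). In A549 with the 18S rRNA covariate TFPI2 (adjusted p = 0.286) and PEG10 (adjusted p = 0.675) lost the call. For PLCL2 both A549 groups (3.83 and 4.28) and the PC9 vector (3.84) were below the spike-in background, so its A549 direction cannot be read. In the same direction, 8 genes rose in both lines against 0.425 expected from the counts (Fisher's exact p = 5.83e-09) and 8 fell against 0.458 (Fisher's exact p = 1.46e-08). In opposite directions, 3 were higher in A549 and lower in PC9 against 0.629 expected (Fisher's exact p = 0.0248), and 1 the reverse against 0.309 (Fisher's exact p = 0.268). Both lines share the same estimate of spread per gene, so a gene with a small estimate is favoured for a call in both. The expected counts ignore this, and these p-values may overstate the overlap. Across all 18244 genes, which are not independent, the changes correlated at r = 0.0918 (Spearman's coefficient 0.052), and 51.6% had the same sign. Over the 496 genes called in A549 the values were r = 0.264 and 0.19 for Spearman's coefficient. The 16 genes shared in direction became 6 without A549 EN2 replicate 1, 13 without A549 EN2 replicate 2, 8 without A549 vector replicate 1, 3 without A549 vector replicate 2, 3 without PC9 EN2 replicate 1, 7 without PC9 EN2 replicate 2, 5 without PC9 vector replicate 1, 4 without PC9 vector replicate 2 and 2 with the 18S rRNA covariate. The count was 1 without the 2 outer A549 arrays, 1 by treat, and 0 by limma on the arrays of each line alone, where 202 genes shared a direction at an unadjusted p below 0.05.

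**Figure D4:**
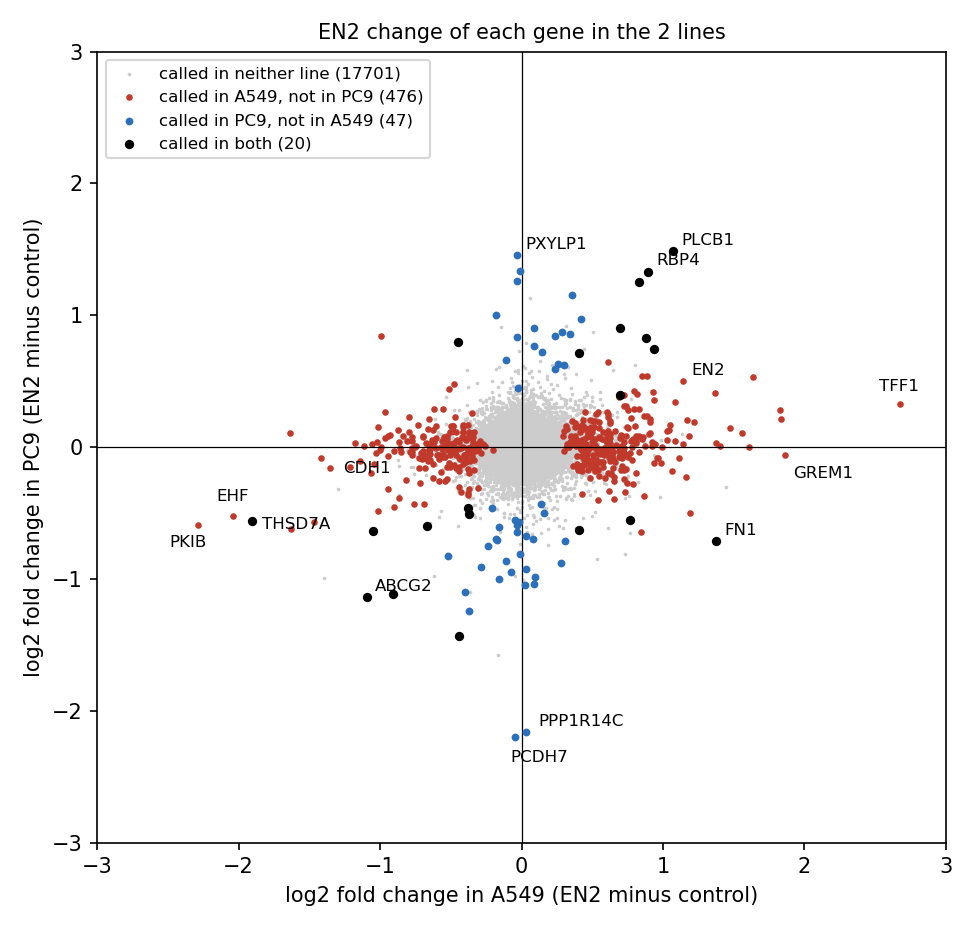
Log2 fold change (EN2 minus vector) of each of 18244 genes in A549 (x axis) against PC9 (y axis), coloured by whether the gene was called in A549, in PC9, in both (20) or in neither. The genes called in both lie mostly along the diagonal, and FN1, TFPI2 and PEG10 lie off it.

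The test of the difference asked which EN2 changes differ in size between the lines. The A549 change of TFF1 exceeded its PC9 change by 2.35 ± 0.15 SE on the log2 scale (limma adjusted p = 0.000667), and that of FN1 by 2.09 ± 0.14 (adjusted p = 0.000667). PPP1R14C (2.19) and PCDH7 (2.15), which fell in PC9, and GREM1 (1.93, adjusted p = 0.047) were the other genes at this end, with SPOCK1, a secreted proteoglycan gene (1.69), higher in A549 (1.19) and at −0.50 in PC9 (adjusted p = 0.083). PCDH7 read 4.61 and 4.65 in the A549 groups, little above the spike-in background of 4.38, so its difference may reflect PC9 alone. At the other end were PI3, the elastase inhibitor elafin (−1.83), ZNF57 (−1.74), PKIB (−1.70), EHF (−1.52), PXYLP1 (−1.49) and THSD7A (−1.34), whose PC9 EN2 level was below background. PI3 fell in A549 (−0.99) and had 0.84 in PC9, which was not called (adjusted p = 0.24). In all, 84 differences were positive and 59 negative among 18244 genes.

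Of 24 epithelial markers, the differences of CDH1 (−1.13), EPCAM (−0.71) and KRT19 (−0.65) were negative, none was positive and 21 did not pass, with 3 negative adjusted over the list alone. Their mean was −0.11 (camera adjusted p = 0.0381; adjusted p = 0.59 with an estimated correlation). The p53 targets had a mean difference of −0.28 (adjusted p = 2.05e-06; adjusted p = 0.3 with an estimated correlation), with MDM2 (−0.92) called among 22, or 5 lower adjusted over the list alone. NRF2 targets had −0.20 (adjusted p = 3.96e-05; adjusted p = 0.59 with an estimated correlation), with GPX2 (−1.03) and AKR1C1 (−0.51) called among 26, or 7 lower adjusted over the list alone. Interferon genes had 0.27 (adjusted p = 9.65e-06; adjusted p = 0.59 with an estimated correlation), with SAMD9 (1.05) called among 38, or 7 higher adjusted over the list alone. YAP/TAZ targets had 0.35 (adjusted p = 0.000287; adjusted p = 0.59 with an estimated correlation), with FOXF2 (0.79) positive, AXL (−0.67) negative and 20 not called, or 5 and 2 adjusted over the list alone.

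No single member was called in the remaining difference lists. TGF-beta/SMAD targets had a mean of 0.27 over 21 members (camera adjusted p = 5.33e-05; adjusted p = 0.3 with an estimated correlation), with 4 positive adjusted over the list alone. NF-kB targets had 0.33 over 31 (adjusted p = 0.000394; adjusted p = 0.59 with an estimated correlation), with 7 positive and 2 negative adjusted over the list alone. Complex I subunits had −0.15 over 36 (adjusted p = 1.98e-07; adjusted p = 0.59 with an estimated correlation) and sterol genes −0.13 over 27 (adjusted p = 0.00981; adjusted p = 0.633 with an estimated correlation), with none adjusted over the list alone. The 143 differing genes became 40 without A549 EN2 replicate 1 or without A549 vector replicate 2, 43 to 46 without any single PC9 array and 10 with the 18S rRNA covariate, and the GREM1 call was kept in 1 of the 8 fits with an array left out, the fit without A549 EN2 replicate 2. Without the 2 outer A549 arrays 0 differences were called by limma (1324 at an unadjusted p below 0.05), and TFF1 (2.23, adjusted p = 0.0719), FN1 (2.06, adjusted p = 0.0881) and PCDH7 (2.27, adjusted p = 0.127) lost the call at a similar size. With that covariate only the epithelial (−0.14) and p53 (−0.41) differences stayed called, the epithelial call ended without 5 of the 8 arrays (lowest −0.11, highest −0.051), the sterol call without 3 (−0.10 to −0.027) and the interferon call without PC9 vector replicate 2 (0.17, adjusted p = 0.0508).

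The average over both lines asked which genes move with EN2 in the lines together. ABCG2 fell by 1.12 (limma adjusted p = 0.000343), EN2 rose by 0.82 (adjusted p = 0.000408), DKK1 by 0.54 and HES1 by 0.84 on the log2 scale. In all, 102 genes rose and 95 fell among 18244. Camera called 11 of 35 lists, and those with the smallest p are described here. NRF2 targets had a mean of −0.19 (camera adjusted p = 6.62e-15; adjusted p = 0.213 with an estimated correlation). Of 26, CYP4F11 (−0.63), GPX2 (−0.62), ALDH3A1 (−0.60), AKR1B10 (−0.44) and AKR1C1 (−0.27) fell, none rose and 21 did not pass, or 15 lower adjusted over the list alone. Hypoxia and glycolysis genes had −0.15 with none of 26 called, adjusted over the list alone included (adjusted p = 0.000816; adjusted p = 0.762 with an estimated correlation). EGFR-RAS-MAPK output genes had 0.15 (adjusted p = 0.000816; adjusted p = 0.648 with an estimated correlation), with the cytokine gene IL11 (0.71) higher and TGFA (−0.53) lower among 28, or 4 and 1 adjusted over the list alone. Epithelial markers had −0.091 (adjusted p = 0.00128; adjusted p = 0.583 with an estimated correlation), with CDH1 (−0.55), EPCAM (−0.42) and KRT19 (−0.38) lower among 24, or 6 lower adjusted over the list alone. The p53 targets had −0.12 (adjusted p = 8.15e-05; adjusted p = 0.213 with an estimated correlation), with MDM2 (−0.38) and DDB2 (−0.34) lower among 22, or 7 lower adjusted over the list alone. The averages of the epithelial and p53 lists rest mainly on A549: in PC9 CDH1 was 0.011, and the PC9 list means were −0.037 for epithelial markers and 0.020 for p53 targets. Among the NRF2 targets, GPX2 was −1.14 in A549 and −0.11 in PC9. The differences between the lines passed limma's test for GPX2 (−1.03) and AKR1C1 (−0.51), so their averages rest mainly on A549 too. The differences of CYP4F11, ALDH3A1 and AKR1B10 did not pass, and AKR1B10 fell in both lines. The count of 197 became 45 with the 18S rRNA covariate, where the EGFR-RAS-MAPK mean turned to −0.050, 112 without PC9 EN2 replicate 1 and 121 without A549 EN2 replicate 1, and the hypoxia call ended without PC9 EN2 replicate 1 (−0.087) or PC9 vector replicate 2 (−0.034).

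The vector controls of the lines were compared to give the level behind each change. A549 was higher in the chemokine gene CXCL5 (12.56 ± 0.046 against 2.78 ± 0.0080, SD, n = 2 arrays each; limma adjusted p = 3.22e-12), IGFBP1 (log2 difference 9.07) and the connexin gene GJA1 (8.93). VIM, the mesenchymal filament vimentin, read 12.85 in A549 and 4.09 in PC9, and the R-spondin gene RSPO3 (8.42) and NNMT (7.43) were also higher in A549. PC9 was higher in CDKN2A, the cell cycle inhibitor gene that A549 is known to lack (12.63 against 4.55), the mucin gene MUC4 (−7.42), HS6ST2 (−6.88), PSCA (−6.62), the long RNA UCA1 (−6.46) and CAPN8 (−6.29). The lower line was below its spike-in background for all of these but VIM, CDKN2A and PSCA. As A549 is known to lack CDKN2A, its level of 4.55 there means that values somewhat above this background need not show expression. Among 18244 genes, 8399 were higher in A549 and 5424 in PC9, or 60.8% higher in A549. That share was 47.9% after quantile normalisation over all arrays (6166 and 6712) and 43.9% after median centring (5820 and 7423), as the median of all genes went from 0.17 to −0.025 and −0.068. Line, culture medium and array processing cannot be separated in this comparison.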

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

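The fit with the 18S rRNA covariate, the slope over all genes, the test of the array batch of each line and the test of the placement of called genes in A549 were chosen only after the results were seen, and the other tests here before. For the genes beside the zinc finger genes both bounds were set before, and the choice to judge by the lower bound was made after.

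The change with EN2 differed between the lines for 143 genes by limma. Among genes higher in A549, the A549 minus PC9 differences were TFF1 2.35, FN1 2.09, GREM1 1.93, SPOCK1 1.69, IQGAP2 1.62, NPTX1 1.61, DIO2 1.55, GASK1B 1.45, XYLT1 1.35, PLPP3 1.33, CA2 1.11 and KLRC1 0.96. IQGAP2, GASK1B, XYLT1 and KLRC1 were below the spike-in background in both PC9 groups, so no PC9 response can be read and these values reflect the A549 change. Among genes lower in A549 they were PI3 −1.83, ZNF57 −1.74, PKIB −1.70, EHF −1.52, THSD7A −1.34, ZNF77 −1.33, TM4SF4 −1.21, ZNF555 −1.20, CDH1 −1.13, GPX2 −1.03 and ANXA10 −1.004. Among genes named for PC9 they were PPP1R14C 2.19, PCDH7 2.15, DMXL2 1.13, NCOA7 1.08, COL4A6 0.99, TACC1 0.87, PXYLP1 −1.49, NFIX −1.34, TNFSF15 −1.29 and COL8A1 −1.18. The genes called in opposite directions gave TFPI2 1.33, PLCL2 −1.25 and PEG10 1.04. TNFSF15 and PLCL2 were below that background in both A549 groups, and THSD7A in the PC9 EN2 group, so these differences are uncertain too. PCDH7 read 4.61 and 4.65 in the A549 groups, little above that background of 4.38, so its difference may reflect PC9 alone. Mean differences of gene lists were YAP/TAZ targets 0.35, NF-kB targets 0.33, interferon genes 0.27, TGF-beta targets 0.27, p53 targets −0.28, NRF2 targets −0.20, complex I subunits −0.15, sterol and fatty acid synthesis −0.13 and epithelial markers −0.11. None of these lists was called with an estimated correlation (adjusted p = 0.3 to 0.633), and the NF-kB difference turned to −0.064 with the 18S rRNA covariate.

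The 18S rRNA control signal differed between the A549 groups and between the replicates of each group. If the A549 calls followed that signal alone, the change between replicates, scaled to the rRNA difference between groups, would be near 1 times the measured change. Over the 496 called genes the median ratio was 0.348 in the control pair (95% interval 0.287 to 0.431) and 0.242 in the EN2 pair. Called genes are chosen for a small spread within groups, which lowers this ratio, so it excludes nothing. With the signal as a covariate 15 of the 496 stayed called, TFF1 and EHF among them, while the median absolute change went from 0.59 to 0.40, the median SE from 0.096 to 0.18, and 493 kept their sign. For genes that lost the call the wider SE leaves EN2 and the gradient open, though FN1 (1.37 and 1.31) hardly moved.

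Genes called in either line changed less in the other, which choosing genes by their call produces in part, so a weaker response of PC9 is not shown. The slope of the PC9 change on the A549 change over 495 genes called in A549 was 0.0891 (95% interval 0.0532 to 0.127), and that of the A549 change on the PC9 change over 67 genes called in PC9 was 0.229. By comparison, the EN2 change in PC9, which did not pass, was 0.436 of that in A549 on the brighter probe set (95% interval 0.21 to 0.706), and over all 18243 genes but EN2, none chosen by a call and with noise removed by products of replicate changes, the slope was 0.0816 (95% interval 0.0596 to 0.104). Products of replicates do not remove a difference that both A549 pairs share, such as the 18S rRNA gradient, which may lower this slope. Its interval is over genes and not over arrays. Whether the response is in proportion to EN2 as this probe set reads it can therefore not be decided here. The other EN2 probe set gives no usable share (0.050 in A549 and 0.16 in PC9), and responses that are not proportional were not tested. The lines also differed by 6.18 in the 18S rRNA control signal, so line biology and array batch cannot be told apart.

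Genes called in the same direction lay beside each other more often than shuffled calls did. In A549 there were 27 such pairs against a shuffled mean of 6.87 and a highest of 20 (permutation p = 1e-04), among them the zinc finger genes ZNF57 and ZNF77. In PC9 there were 4, against a mean of 0.119 and a highest of 3 (permutation p = 1e-04), and 1e-04 is the smallest value that 10000 shuffles can give. The PC9 pairs were CDIN1 with MEIS2, SPP1 with ABCG2, AKR1B10 with AKR1B15, and COL4A6 with COL4A5. AKR1B10 with AKR1B15 was also a pair in A549. Probes shared by related neighbours were not tested. Calls were shuffled over all 18192 placed genes, dim ones included, which may lower the shuffled counts. The 494 other ZNF genes had a median A549 change of 0.061, so a family-wide cross-hybridisation is not the cause, while probes shared by ZNF57, ZNF77 and ZNF555 alone were not tested. Their ratio to the rRNA gradient, −0.040, excludes nothing. With the covariate ZNF57 (−2.01) and ZNF77 (−1.57) stayed called, and ZNF555 kept its size (−1.38) without a call. A linear effect of that signal alone is therefore not the cause for ZNF57 and ZNF77. Other differences in RNA quality or batch between the A549 groups are not excluded. The 11 genes beside and between the 3 had a median of −0.13 (95% interval −0.229 to −0.0652). This lies above the −0.5 that a loss of the longer stretch was said to need, so a fall of that size across these neighbours is not the cause. A smaller fall of the longer stretch stays open, as the interval reaches past −0.2, the other bound, 10 of the 11 were below 0, and THOP1 (−0.38) and TLE5 (−0.32), chosen after their values were seen, were called. ZNF556, the only tested gene between the 3 (4.17 and 4.30), and GNA15 (3.40 and 3.47) were below the spike-in background in both A549 groups. They could not show a fall, so a loss limited to the 3 genes and the stretch between them was not tested.

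Regrouping the arrays within a line gives too few splits for a share below 0.05. In A549, 1 of 3 splits reached the real count of 496, and the highest other count was 0 by limma, where 876 and 237 genes had an unadjusted p below 0.05. In PC9, 1 of 3 reached 67, and the highest other was 4. For the average, 1 of 18 reached 197, and the highest other was 143. That split kept the A549 groups and swapped the PC9 groups, which makes it the test of the difference between the lines. It is therefore no regrouping without an effect. Other splits that kept the A549 groups also keep the A549 changes and called 32 to 72 genes. Splits that broke the A549 groups called at most 6 by limma.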

How the results depend on the processing

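The fits with the 18S rRNA covariate and without the 2 outer A549 arrays were chosen only after the result was seen, and all others before.

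Constant or robust prior variance, quantile normalisation and median centring left every count within 1.5 times. Testing only the brighter part of the genes gave 17 higher in PC9 and 7164 between the controls, by construction from fewer genes. With the mean of probe sets, EN2 was 0.60 in A549 and 0.33 in PC9, 26 fell in PC9 and 10 were shared by the lines. Testing every probe set counts probe sets, not genes: 511 higher and 465 lower in A549, 41 and 97 in PC9, 266 differences, 485 on average, 36735 between controls, and 11 lists in PC9 and 16 for the difference. The arrays of a line alone, with fewer arrays, gave 51 and 41 in A549, 7 and 16 in PC9 and 0 shared by limma (202 at unadjusted p below 0.05). The replicate block gave 538 and 334 in A549, 338 on average and 27 shared, with all 496 genes among the A549 calls. The labels do not say whether replicate numbers pair the samples. Replicate differences of the EN2 and vector groups correlated at r = 0.334 in A549 and 0.0767 in PC9. A pairing in A549 therefore stays open, though replicate 1 also had the lower 18S rRNA signal in both A549 groups. Limma's treat at 1.2-fold, a stricter test by construction, gave 43 and 34 in A549, 5 and 10 in PC9, 35 differences, 37 on average and 1 shared. Camera with an estimated correlation called 0 lists in A549, 0 in PC9, 0 for the difference and 0 on average (unadjusted 4, 0, 2 and 3). Fry called 6, 0, 0 and 4 (unadjusted 11, 1, 8 and 7).

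With the 18S rRNA covariate 5 rose and 15 fell in A549, with 10 differences, 45 on average, 2 shared and 7 lists in A549, and EN2 was 1.11 in A549. Those 7 lists include the G2/M, S-phase and heat shock lists, which were not called without the covariate, so the count is not one of lists that stayed called. List means turned to −0.13 for NF-kB, −0.18 for EGFR-RAS-MAPK and −0.051 for YAP/TAZ in A549, and −0.064 for the NF-kB difference. On average over the lines the S-phase mean was −0.11 (camera adjusted p = 0.0106, or 0.762 with an estimated correlation). It turned to 0.17 with the covariate, called in that direction (camera adjusted p = 7.19e-06). The other averages turned from 0.0785 to −0.030 for interferon, from 0.15 to −0.050 for EGFR-RAS-MAPK and from 0.13 to −0.053 for YAP/TAZ. Without the 2 outer A549 arrays 9 rose and 16 fell, with 0 differences by limma (1324 at unadjusted p below 0.05), 42 on average, 1 shared and EN2 at 1.15. There EGFR-RAS-MAPK in A549 turned to −0.016 and the S-phase average to 0.046. Fewer arrays lower the power by construction. The covariate differed between the A549 groups, and there the median SE of the 496 called genes went from 0.096 to 0.18. In PC9, where the signal hardly varied, 33 genes rose and 59 fell with the covariate. All 67 PC9 calls were kept, and their median SE went from 0.097 to 0.092. The cause of the turned list means was not tested.

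Leaving out each array in turn, 54 to 369 genes rose and 58 to 254 fell in A549, and 7 to 12 rose and 12 to 18 fell in PC9. Differences ran from 40 to 124, averages from 112 to 225, shared genes from 3 to 13 and controls from 12575 to 13815. Lists called ran from 11 to 14 in A549, 2 to 7 in PC9, 8 to 12 for the difference and 5 to 14 on average. EN2 ran from 1.10 to 1.19 in A549 and from 0.42 to 0.57 in PC9. In PC9 the S-phase mean ran from −0.24 to 0.051 and the hypoxia mean from −0.38 to 0.084. The lone array left in a group is assumed to vary like the other groups, and the cause of the ranges was not tested.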

Other observations

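The fits with the 18S rRNA covariate and without the 2 outer A549 arrays were chosen only after the result was seen.

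Genes of neural and lung identity changed singly in A549. SYT1, a synaptic vesicle gene, rose by 0.99 (limma adjusted p = 0.00109), NR4A2, a nuclear receptor of midbrain dopamine neurons, by 0.96 (adjusted p = 0.00176) and GATA6, a lung endoderm transcription factor, by 0.85 (adjusted p = 0.0232) on the log2 scale. Each was the only called member of its list in A549, and neither the neuroendocrine list (camera adjusted p = 0.271) nor the midbrain-hindbrain list (adjusted p = 0.271) nor the lung lineage list (adjusted p = 0.987) was called. The difference between the lines passed for GATA6 (1.49), SYT1 (1.11) and NR4A2 (1.04). In A549 with the covariate, GATA6 was 0.33 (adjusted p = 0.988), NR4A2 0.60 (adjusted p = 0.571) and SYT1 0.97 (adjusted p = 0.288), and without the 2 arrays 0.59, 0.77 and 0.94, none called.

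Genes of the cell cycle, heat shock and Notch lists were called singly in A549, while the lists were not. CDK1, the mitotic kinase, rose by 0.55 among 29 G2/M genes (camera adjusted p = 0.63), and S-phase genes had a mean of −0.12 with none of 28 called (adjusted p = 0.152). These lists depended on the 18S rRNA signal: with the covariate the A549 means were 0.66 for G2/M genes (adjusted p = 5.9e-31), 0.42 for S-phase genes (adjusted p = 9.72e-11) and −0.57 for heat shock genes (adjusted p = 2.06e-11). Without the 2 arrays they were 0.37, 0.19 and −0.27, all called, so their direction with EN2 in A549 is not settled. HSPB1, a small heat shock protein gene, fell by 0.72 among 21 heat shock genes (adjusted p = 0.754). Among 22 Notch genes HES1 and HES4 (0.61) rose (adjusted p = 0.63). With the covariate HES4 was 0.14 (adjusted p = 1), CDK1 0.63 (adjusted p = 0.432) and HSPB1 −0.49 (adjusted p = 0.379). Without the 2 arrays HES4 was 0.35, CDK1 0.59 and HSPB1 −0.58, none called, and on the A549 arrays alone HES4 (adjusted p = 0.162) and CDK1 (adjusted p = 0.0719) were not called. In PC9 the receptor gene AXL rose by 0.76 and TIMP3, an inhibitor of metalloproteinases, by 0.84, and the cofactor gene MEIS2 fell by 0.81, while their lists were not called.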
